A study of Rattus norvegicus with 4 samples.

How the data were processed

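The series held 4 arrays of RNA from the hippocampal CA3 area of Sprague-Dawley rats, taken 24 h after injection into the hippocampus of PBS (the vehicle), kainic acid (KA, an agonist of kainate-type glutamate receptors), KA together with the peptide NAP (a short fragment of activity-dependent neuroprotective protein, ADNP), or NAP alone. Each group had 1 array. The labels name no second sample of any group and do not say whether an array holds RNA of 1 animal or of a pool.

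Per the labels' protocols, RNA was extracted with a column kit, all samples at the same time, and 500 ng of total RNA per sample went through 2 rounds of amplification to biotin-labelled cRNA for an Affymetrix array. That procedure favours the 3′ ends of transcripts. Per the submitters' processing notes, signal intensities were computed with MAS5, which summarises the probe pairs of a probe set into 1 intensity. The MAS5 version, its background settings and its detection calls are not given in the sources used here. The deposited intensities were linear whole numbers, with 0 negative values and 1180 zeros among 31099 probe sets on 4 arrays. The mean intensity after removal of 2% of the values at each end was 250 on every array, so the authors' scaling had already set the arrays to one level. All columns of the table belonged to the 4 samples. Detection calls and scan dates were not used here, so signal over background and scan batch were not examined.

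Gene names came from the platform annotation supplied with the table. Of the probe sets, 20832 had 1 gene symbol, 436 had several and were not named, 9780 were not listed there, and 57 were controls. An Entrez identifier of 20764 singly named probe sets was present in the GRCr8 gene table, whose symbols were used. No genome build is named for the deposited table, so no coordinates are given. A gene took its value from its brightest probe set over the 4 arrays, which gave 14217 genes. The analysis used log2(intensity + 10), where 10 is the 20th percentile of all values in the table. Fold differences are on that scale and understate those of dim genes. Among the named genes, Ccl7, Clec7a, Hbb, Htr5b and Plac9 had an intensity of 10 or less on 1 array, so the size and rank of their differences from that array depend on the pseudocount. Genes entered when the mean intensity of their probe set was above 62.75, the median over all probe sets other than controls, which left 9489 genes. Among these, 2080 had several probe sets past the filter.

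With 1 array per group there is no replicate error, and no test between groups, p-value or standard error is given. A difference of 2-fold or more is a fixed rule of size. 4 differences were formed: KA minus PBS, KA+NAP minus NAP, KA+NAP minus KA, and NAP minus PBS. The first pair shares no array, and neither does the second pair, so a correlation across genes within a pair is free of shared-array noise. KA minus PBS and KA+NAP minus KA share the KA array, and their correlation was set beside 100 simulations of noise alone, drawn by resampling NAP minus PBS within 20 intensity bins. The average KA effect is the mean of the first pair, and the interaction is KA+NAP minus NAP less KA minus PBS. These 2 contrasts are orthogonal when arrays have equal noise, so the interaction was read over genes chosen on the average KA effect.

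37 gene lists were fixed before the data were examined, as were the comparisons, the settings and the rule for naming genes. 35 of them had 3 or more members past the filter. Medians and shares of a list cover only its members past the filter. Of the members on the array, 15 of 26 cytokines and chemokines, 7 of 14 infiltrating myeloid cell markers and 14 of 20 cell cycle genes passed. Because the filter uses the mean over the 4 arrays, a gene dim without KA can pass through its KA intensity. The median difference of a list was ranked among 10000 random lists of the same size matched on mean intensity. A median outside the central 95% of these is described as outside the random range. This ranking describes the 4 arrays and is no test of the conditions. By chance about 1.75 of the 35 lists would lie outside in each comparison, and more where the members of a list vary together. 3 further marker lists (CA1 pyramidal, dentate granule cell and border macrophage markers) were added after the data had been seen, as was the minimum size for a difference between the KA effects to be singled out.

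Genes were named when they were among the 12 highest and 12 lowest average KA effects with at least 2-fold in one direction in both KA differences, the 8 highest and 8 lowest differences of KA+NAP minus KA, the 5 highest and 5 lowest of NAP minus PBS, the 8 highest and 8 lowest interactions, or the 4 largest differences of a list in a comparison, or were on a list of 16 genes named in advance. 1 of those 16 had no value and was not analysed here. Where a count of 5 or fewer list members is given, its members are named even outside this rule, and were then chosen after their values were seen.

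The procedure was tested on simulated data with 100 seeded changes of each of 2 sizes among 9489 genes. For changes of 1.5 on the log2 scale, 97% were recovered at 2-fold in a single KA minus PBS difference and 94% in both KA differences. For changes of 2.5, both shares were 98%. Among the unchanged genes, 121 reached 2-fold in KA minus PBS and 0 reached it in one direction in both KA differences. 0 of 40 unchanged lists fell outside the random range. Those lists held random genes with independent noise, so this result does not cover lists whose members vary together. The simulated noise came from NAP minus PBS and therefore includes any difference between those animals.

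Alternatives to the scaling (array medians, quantiles, trimmed means), the pseudocount, the filter, the choice of probe set, the fold threshold and the contrast used to choose genes were fixed in advance. Use of the other control array was added after the data were seen. Leaving out a replicate was not possible. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The small number of arrays limits the precision of every value.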

Results

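Gene expression in the rat hippocampal CA3 area was measured on 4 arrays, 1 each from animals injected with PBS, KA, KA+NAP or NAP. The design addresses which transcripts differ 24 h after the excitotoxin and how the neuroprotective peptide bears on them. Every value below is from a single array or from a difference of single arrays, so none carries a replicate error. The median intensity over all probe sets was 58 on the PBS array, 61 on the KA array, 65 on the KA+NAP array and 61 on the NAP array. Across the 9489 genes past the filter, log2 intensities correlated at r = 0.98 between PBS and NAP and at r = 0.97 between KA and KA+NAP. The correlation was 0.93 between PBS and KA and also 0.93 between NAP and KA+NAP. The 3′ to 5′ intensity ratio of the beta-actin control probe sets was 14.1 on the PBS array, 11.4 on the KA array, 15.5 on the KA+NAP array and 7.92 on the NAP array. The corresponding GAPDH ratios lay between 1.31 and 1.56, and those of hexokinase were 8, 6.68, 5.5 and 6.05 in the same order of arrays. The hexokinase 5′ intensities were 27, 34, 34 and 42, below the filter threshold of 62.75, so the hexokinase ratios rest on dim signal.

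KA was compared with PBS to describe the response to the toxin alone. Reactive astrocyte, matrix and cytokine and chemokine genes had medians above the PBS array. Ccl2, a monocyte chemoattractant, had an intensity of 40 with PBS and 5786 with KA, a log2 difference of 6.86. Its neighbour in function Ccl7 differed by 5.96, the small heat shock protein Hspb1 by 5.35 (123 to 5423), the collagen cross-linking enzyme Lox by 5.66, and the neuropeptide precursor Trh by 5.90. The lowest differences were those of the neuropeptide gene Nts at −3.48 (616 to 46), the serotonin receptor gene Htr5b at −3.33 (191 to 10) and the gap junction gene Gjb6 at −2.78 (956 to 131). In all, 466 genes were at least 2-fold higher and 227 at least 2-fold lower on the KA array. Simulations of noise drawn from NAP minus PBS gave an average of 106 genes at 2-fold, both directions counted together. NAP minus PBS, the source of that noise, itself had 123 such genes. With the NAP array in place of the PBS array, 302 genes were at least 2-fold higher.

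Reactive astrocyte genes had a median log2 difference of 2.34 in KA minus PBS, outside the random range, and 12 of 16 were at least 2-fold higher. The hyaluronan receptor Cd44 differed by 3.72, the metalloproteinase inhibitor Timp1 by 3.39 and Emp1 by 3.28. The intermediate filament gene Vim differed by 2.10 and Gfap, already at 5744 with PBS, by 0.50. Extracellular matrix and proteolysis genes had a median of 2.41 with 12 of 16 at least 2-fold higher, among them Spp1 (osteopontin) at 4.27 and Tnc (tenascin C) at 3.49. Of 26 cytokines and chemokines on the array, 15 passed the filter, which admits genes dim without KA when KA raises them. These had a median of 1.20, with 9 of 15 at least 2-fold higher and 1, the B-cell chemokine Cxcl13, lower at −1.70. With the filter at the 75th percentile that median was 4.27. Cell cycle genes had a median of 1.24 with 9 of 14 at least 2-fold higher, including Mcm5 at 1.77 and Top2a at 1.51. Activity-regulated neuropeptides and growth factors had a median of 1.13 with 10 of 16 at least 2-fold higher. Inhba differed by 3.18, Npy by 2.45 and Penk by 2.23, and Bdnf was at 655 with PBS and 1412 with KA.

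Immediate early genes were divided on the KA array, with a median of 0.32 that was outside the random range. 7 of 20 were at least 2-fold higher, including Atf3 at 2.61, Myc at 2.31, Fos at 2.29 and Fosl1 at 2.17. 2 were at least 2-fold lower, the nuclear receptors Nr4a3 at −1.74 and Nr4a2 at −1.12. Heat shock proteins had a median of 0.32, and 4 of 11 were at least 2-fold higher: Hspb1, Hspb8 at 2.35, the co-chaperone Bag3 at 1.62 and Hspa1a at 1.35. Oxidative stress genes and metallothioneins had a median of 0.33 with 1 of 13 at least 2-fold higher, haem oxygenase 1 (Hmox1) at 2.65. Pro-apoptotic and p53 target genes had a median of 0.25, inside the random range, with 3 of 12 at least 2-fold higher (Gadd45a at 3.05, Cdkn1a at 1.26 and Aen at 1.06) and 1 lower (Bbc3 at −1.04). Of 7 anti-apoptotic genes, 3 were at least 2-fold higher (Cflar at 1.30, Mcl1 at 1.21 and Bcl2a1 at 1.11), and their median of 0.15 was inside the random range. Ribosomal protein genes had a median of 0.18, outside the random range, and none of the 19 reached 2-fold.

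Microglia and macrophage markers separated into higher and lower genes in KA minus PBS. Their median was 0.50, outside the random range, with 7 of 19 at least 2-fold higher, led by the endotoxin co-receptor Cd14 at 2.74, the Fc receptor Fcgr2b at 2.13 and the NADPH oxidase subunit Cybb at 1.73. Cd68 differed by 1.30 and Aif1 by 0.10. Markers of resting microglia lay below, with a median of −1.39 over 4 genes. 3 of them were at least 2-fold lower: the purinergic receptor P2ry12 at −2.16 (1071 to 232), Tmem119 at −1.55 and Gpr34 at −1.23. Infiltrating myeloid cell markers had a median of 0.96, and 3 of 7 were at least 2-fold higher (S100a9 at 2.45, Mmp9 at 2.31 and S100a8 at 1.41). With the filter at the 75th percentile that median was −0.0364. The haemoglobin gene Hbb was at 5 on the PBS array and 186 on the KA array. Its probe set can also bind related transcripts.

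Lists of neuronal and general astrocyte markers had medians below 0 in KA minus PBS. Pan-neuronal markers had a median of −0.36, outside the random range, and none of the 16 reached 2-fold. Elavl4 was at −0.92, Rbfox3 (NeuN) at −0.82 and Snap25 at −0.39. Excitatory neuron and CA3 markers had a median of −0.56 with none of 12 at 2-fold. Neurod1 was at −0.94, Amigo2 at −0.81, Bok at −0.76 and the kainate receptor subunit Grik4 at −0.15. CA1 and dentate gyrus markers had a median of −1.11, and 5 of 9 were at least 2-fold lower: Ccn3 at −2.50, Fibcd1 at −2.20, Mpped1 at −2.08, Pou3f1 at −2.04 and Wfs1 at −1.11. Lower values than PBS were not limited to KA. Of 7 CA1 pyramidal markers, listed after the data were seen, 6 were also lower with NAP alone (median −0.55). The fixed list, which also holds dentate genes, had a median of 0.33 there. In KA+NAP minus NAP, the 7 CA1 markers had a median of 0.38, inside the random range. Synaptic genes had a median of −0.55, voltage-gated ion channels −0.53, ionotropic glutamate receptors −0.36 and microtubule and ADNP-related genes −0.31, each outside the random range. Only 1 gene over these 4 lists was at least 2-fold lower, the PACAP receptor Adcyap1r1 at −1.18. Adnp itself differed by 0.17, and 2 of its 3 probe sets past the filter lay above 0. General astrocyte markers had a median of −0.39, with Gjb6 and the glycolytic enzyme Aldoc (−1.07) at least 2-fold lower among 13.

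KA+NAP was compared with NAP to describe the toxin's effect in animals that also had the peptide. The highest log2 differences were 5.27 for Ccl7, 5.11 for Trh, 4.79 for Ccl2 and 4.32 for Spp1. At the lower end, Gjb6 was at −2.38, the epoxide hydrolase Ephx2 at −2.45 and Alb at −3.08, from 168 to 11. In all, 537 genes were at least 2-fold higher and 229 at least 2-fold lower. Across the 9489 genes, this difference and KA minus PBS, which share no array, correlated at Pearson r = 0.70 and Spearman rho = 0.61, and genes are not independent replicates. Of the 466 genes at least 2-fold higher in KA minus PBS, 442 lay above 0 with NAP, 297 were at least 2-fold higher there and 2 were at least 2-fold lower. Of the 227 lower genes, 203 lay below 0 with NAP, 84 were at least 2-fold lower and 5 at least 2-fold higher. Independent lists of these sizes would share 26.4 higher and 5.48 lower genes.

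The genes with the highest average KA effects at 2-fold in both differences were Ccl2, Ccl7, Trh, Tubb6, Lox, Hspb1, Spp1, Tnfrsf12a, Tcim, Cd44, Fbln2 and Flnc. Tubb6, a beta tubulin, differed by 5.02 without and 3.81 with NAP, and the TWEAK receptor Tnfrsf12a by 3.63 and 3.32. Fbln2 (fibulin 2) differed by 3.37 and 3.33, and Flnc (filamin C) by 3.63 and 2.90. The lowest were Gjb6, Ephx2, Nat8f5, Sncg, Alb, Plac9, Cxcl13, Hlf, Sult1a1, Ccn3, Cldn10 and B3gat2. Sncg (gamma-synuclein) was at −2.44 without and −2.39 with NAP. Hlf was at −2.77 and −1.80, and the tight junction gene Cldn10 at −2.65 and −1.71. Among genes with several probe sets past the filter, 111 were at least 2-fold apart in KA minus PBS. Of these, 104 had all probe sets on one side of 0, and 56 reached 2-fold in all of them. In KA+NAP minus KA, 13 of 17 such genes had all probe sets on one side and 4 reached 2-fold in all. In NAP minus PBS, these counts were 12 of 13 and 4.

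**Figure D1:**
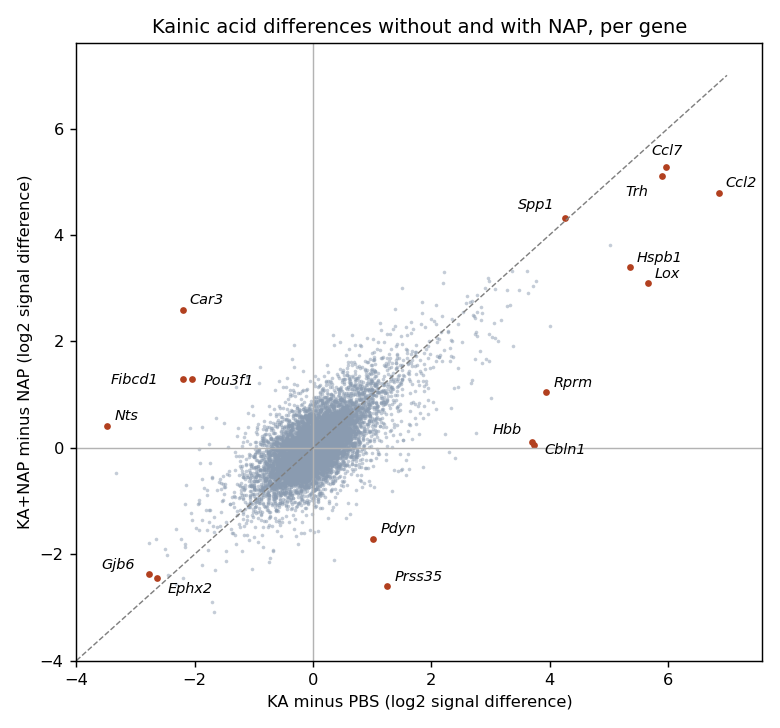
Each point is 1 of 9489 genes, with the log2 intensity difference KA minus PBS on the horizontal axis and KA+NAP minus NAP on the vertical axis; the dashed line marks equal differences and red points are named genes. The differences correlate at r = 0.70 across genes, while Car3, Fibcd1, Pou3f1, Prss35 and Pdyn lie in the quadrants of opposite sign.

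Injury-related gene lists were also high in KA+NAP minus NAP. Reactive astrocyte genes had a median of 2.00, matrix genes 1.82, cell cycle genes 1.34, cytokines and chemokines 1.22 (4.32 with the filter at the 75th percentile), and infiltrating myeloid cell markers 0.60, each outside the random range. Heat shock proteins had a median of 0.57 with Hspa1a at 2.23, and oxidative stress genes 0.31 with Hmox1 at 2.74. Ribosomal protein genes were at 0.36, pro-apoptotic genes at 0.41 and anti-apoptotic genes at 0.59. Immediate early genes had a median of 0.88, with 8 of 20 at least 2-fold higher and Nr4a3 lower at −1.17. Microglia and macrophage markers had a median of 0.97 with 9 of 19 at least 2-fold higher. Resting microglia markers had a median of −0.51, outside the random range, with P2ry12 (−1.05) the 1 gene at 2-fold. Interferon response genes had a median of 0.52 with 3 of 14 at least 2-fold higher (Irf9 at 1.62, Ifitm3 at 1.17 and Usp18 at 1.14). Meningeal and fibroblast markers were at −0.72 with Igf2 (−1.15) and Ogn (−1.04) at least 2-fold lower, outside the random range, and at 0.30 with the filter at the 75th percentile. This list was at −0.04 in KA minus PBS, inside the random range, and at 1.16 in NAP minus PBS. Its −0.72 is therefore relative to a NAP array that lay above the PBS array. The 3 choroid plexus and ependymal markers had a median of −0.65, outside the random range, with Ttr at −2.10, Enpp2 at −0.65 and Foxj1 at 0.58. Complement and antigen presentation genes were at 1.06 with 6 of 11 at least 2-fold higher, against a median of 0.25 and none in KA minus PBS. The median interaction of this list was 0.31, inside the random range. Activity-regulated neuropeptides and growth factors were at 0.57 with 6 of 16 at least 2-fold higher and 1 lower, Pdyn (prodynorphin) at −1.71.

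On the neuronal side of KA+NAP minus NAP, excitatory neuron and CA3 markers had a median of −0.72, and 3 of 12 were at least 2-fold lower (Coch at −1.36, Cpne4 at −1.04 and Neurod1 at −1.03). Pan-neuronal markers were at −0.33, with Nefm at −1.17 and Syt1 at −1.02 the 2 genes at 2-fold. Voltage-gated ion channels were at −0.56, microtubule and ADNP-related genes at −0.33, ionotropic glutamate receptors at −0.30, synaptic genes at −0.29 and general astrocyte markers at −0.39, each outside the random range. GABA-A receptor subunits were at −0.93 with 3 of 7 at least 2-fold lower (Gabrd at −1.64, Gabra2 at −1.25 and Gabrb1 at −1.03), against −0.04 in KA minus PBS. CA1 and dentate gyrus markers were at −0.24, inside the random range, with Fibcd1 at 1.30, Pou3f1 at 1.28 and Ccn3 at −1.90. In both KA differences, GABAergic interneuron, oligodendrocyte and endothelial markers and ER stress, glycolysis, cholesterol synthesis, respiratory chain and housekeeping genes had medians between −0.11 and 0.22, all inside the random range.

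KA+NAP was compared with KA to describe the peptide's effect in injured tissue. The KA+NAP array was higher in antigen presentation, macrophage and CA1 genes and lower in several neuropeptide genes. The 8 highest differences were Nts (neurotensin, 46 to 483) at 3.14, Hbb at 2.99, the MHC class II gene RT1-Ba at 2.72, Lcn2 at 2.48, the MHC class II gene RT1-Da at 2.44, Pou3f1 at 2.29, the beta-glucan receptor Clec7a at 2.11 and Plac9 at 2.06. The value and rank of Plac9 depend on the pseudocount, because its intensity was 2 with KA and 40 with KA+NAP. The 8 lowest were Cbln1 at −2.48, Ttr at −2.43, Acvr1c at −2.41, Rprm at −2.27, Lox at −2.10, Pdyn at −2.03, Epcam at −2.02 and Sorcs3 at −1.95. In all, 144 genes were at least 2-fold higher and 57 at least 2-fold lower. The correlation with KA minus PBS was −0.12, and simulated noise with the shared KA array gave −0.50. Those simulations held no KA effect, which by itself weakens the correlation, so the 2 correlations are not comparable. The covariance was −0.026 against a simulated −0.052. The simulated noise came from NAP minus PBS and includes any difference between those animals. Neither value decides whether the peptide lowered KA effects.

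Microglia and macrophage markers had a median of 0.99 in KA+NAP minus KA, with 9 of 19 at least 2-fold higher. Cybb was at 2.03, Cd68 at 1.60, Itgam at 1.46, Cd53 at 1.40 and Aif1 at 1.11. Complement and antigen presentation genes had a median of 0.88 with 5 of 11 at least 2-fold higher (RT1-Ba, RT1-Da, Cd74 at 1.91, RT1-Db1 at 1.66 and Psmb9 at 1.05). Infiltrating myeloid cell markers were at 0.94, meningeal and fibroblast markers at 0.71, resting microglia markers at 0.62, cell cycle genes at 0.60, endothelial markers at 0.57, matrix genes at 0.42, interferon response genes at 0.40, reactive astrocyte genes at 0.28 and ribosomal protein genes at 0.22, each outside the random range. The Hbb intensity stood at 1549 on the KA+NAP array and 186 on the KA array beside these groups. CA1 and dentate gyrus markers had a median of 0.95 with 4 of 9 at least 2-fold higher, namely Pou3f1, Mpped1 at 1.76, Fibcd1 at 1.53 and Ccn3 at 1.07. With the filter at the 75th percentile that median was −0.013.

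Activity-regulated neuropeptides and growth factors had a median of −0.17 in KA+NAP minus KA, outside the random range, and 4 of 16 were at least 2-fold lower. Penk was at 1635 with KA and 429 with KA+NAP, against 341 with PBS and 358 with NAP. Bdnf was at 1412 with KA, 594 with KA+NAP, 655 with PBS and 642 with NAP. Npy was at 4142 with KA and 1868 with KA+NAP, and Pdyn at 2330 and 561. GABA-A receptor subunits had a median of −0.49 with 2 of 7 at least 2-fold lower (Gabra2 at −1.26 and Gabra4 at −1.16). Choroid plexus and ependymal markers had a median of −0.44 over 3 genes, with Ttr at −2.43, Enpp2 at −0.44 and Foxj1 at 0.40. Voltage-gated ion channels were at −0.20 and cholesterol synthesis genes at −0.21, outside the random range with no gene at 2-fold. Pan-neuronal markers were at 0.00, excitatory neuron and CA3 markers at −0.10, synaptic genes at 0.07, ionotropic glutamate receptors at 0.11, general astrocyte markers at 0.09 and microtubule and ADNP-related genes at −0.02, all inside the random range. The lists not named here were also inside it. Rbfox3 was at 0.34, Snap25 at 0.03, Grik4 at −0.90 and Adnp at −0.02, a sign held by 1 of the 3 Adnp probe sets past the filter. Pro-apoptotic genes were at −0.09, anti-apoptotic genes at 0.13, heat shock proteins at 0.14, oxidative stress genes at 0.15, immediate early genes at 0.20 and cytokines and chemokines at 0.26, also inside it. With the filter at the 75th percentile the last of these was −0.0525.

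**Figure D2:**
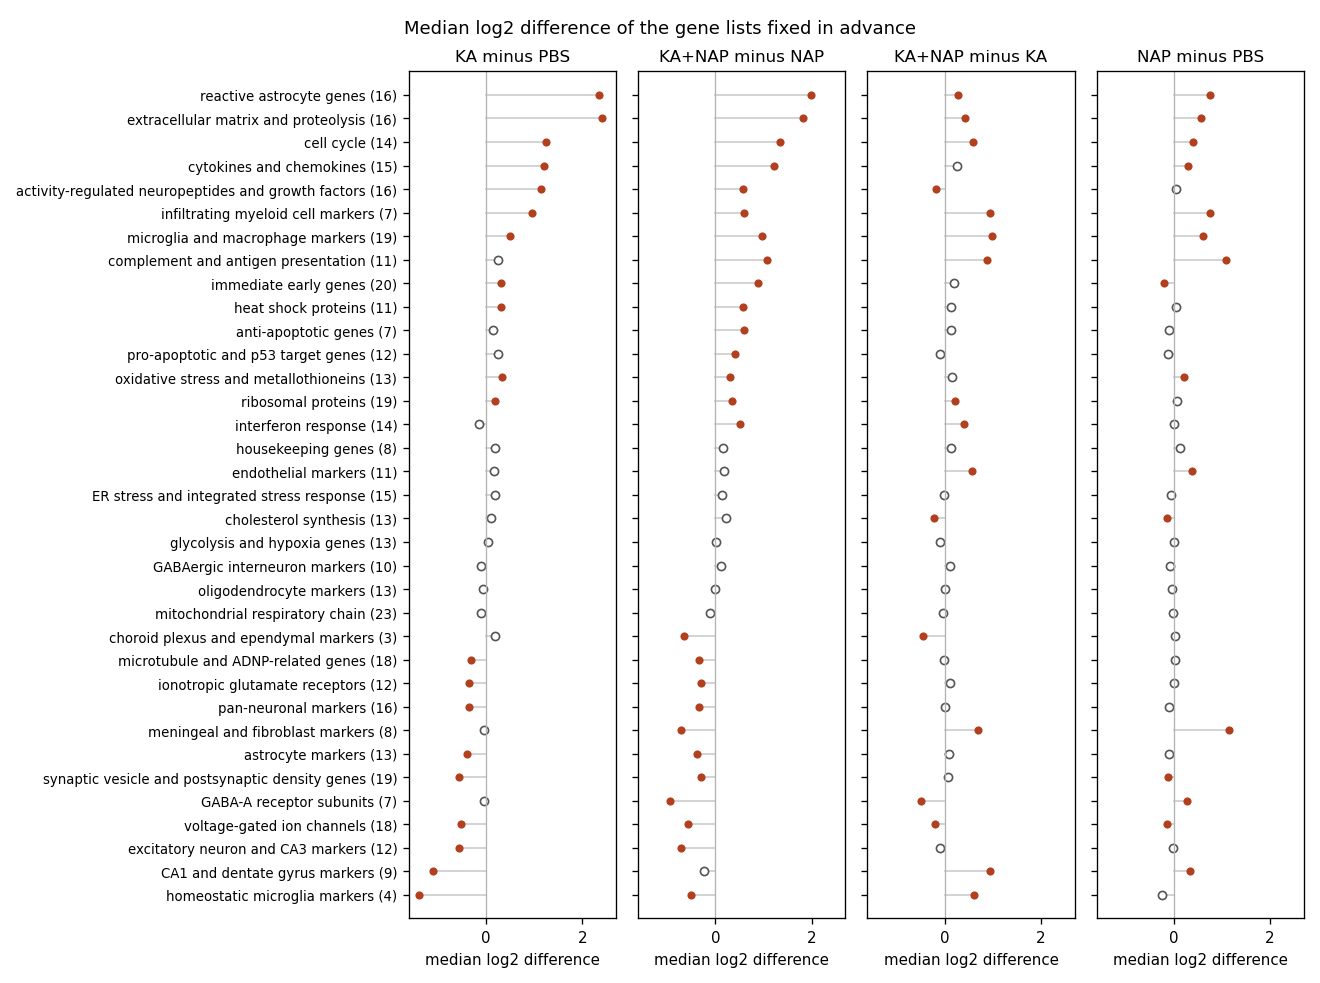
Median log2 intensity difference (horizontal axis) of the 35 gene lists with 3 or more measured members, whose number is in parentheses, in the 4 comparisons; filled points lie outside and open points inside the central 95% of 10000 matched random lists. Reactive astrocyte and matrix genes are highest in both KA comparisons (2.34 and 2.41 without NAP), and microglia and macrophage markers lie to the right in all 4.

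NAP was compared with PBS to describe the peptide without the toxin. Hbb and groups of inflammatory and meningeal genes were higher on the NAP array. Hbb was at 5 with PBS and 1430 with NAP. Its log2 difference of 6.58 depends on the pseudocount. Lcn2 (lipocalin 2) was at 2.76, the cholesterol exporter Abca1 at 2.41, Clec7a at 2.35 and Plac9 at 2.31. The 3 Abca1 probe sets past the filter were all higher in NAP minus PBS, but did not share a sign in KA minus PBS. The 5 lowest differences were the carbonic anhydrase Car3 at −3.03, Fibcd1 at −1.98, Cwc25 at −1.83, Pts at −1.47 and Nkain3 at −1.26. In all, 100 genes were at least 2-fold higher and 23 at least 2-fold lower. NAP minus PBS and KA+NAP minus KA, which share no array, correlated at r = 0.12 and rho = 0.04 across genes. They had 30 genes in common at 2-fold higher and 0 at 2-fold lower, where independent lists would share 1.52 and 0.14.

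Meningeal and fibroblast markers had a median of 1.16 in NAP minus PBS with 5 of 8 at least 2-fold higher: Ogn at 1.76, Col1a2 at 1.72, Igf2 at 1.69, Col3a1 at 1.22 and Mgp at 1.09. Complement and antigen presentation genes had a median of 1.09 with 6 of 11 at least 2-fold higher, led by Cd74 at 1.60, C3 at 1.55, RT1-Ba at 1.41 and the complement inhibitor Serping1 at 1.34. Reactive astrocyte genes were at 0.75, and 4 of 16 were at least 2-fold higher (Lcn2, Hspb1 at 2.07, Timp1 at 1.90 and Cp at 1.52). Infiltrating myeloid cell markers were at 0.75, microglia and macrophage markers at 0.61, matrix genes at 0.56, cell cycle genes at 0.41, endothelial markers at 0.39, cytokines and chemokines at 0.31, GABA-A receptor subunits at 0.27 and oxidative stress genes at 0.21, each outside the random range. CA1 and dentate gyrus markers had a median of 0.33, above the random range, although the 2 members at 2-fold were lower (Fibcd1, and Pou3f1 at −1.03). Ccl2 was at 181 with NAP against 40 with PBS. Immediate early genes were at −0.20, cholesterol synthesis genes at −0.14, voltage-gated ion channels at −0.13 and synaptic genes at −0.12, outside the range on the lower side with no gene at 2-fold. Adnp was at 1386 on both arrays in the brightest of its 3 probe sets past the filter. The other lists were inside the random range.

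**Figure D3:**
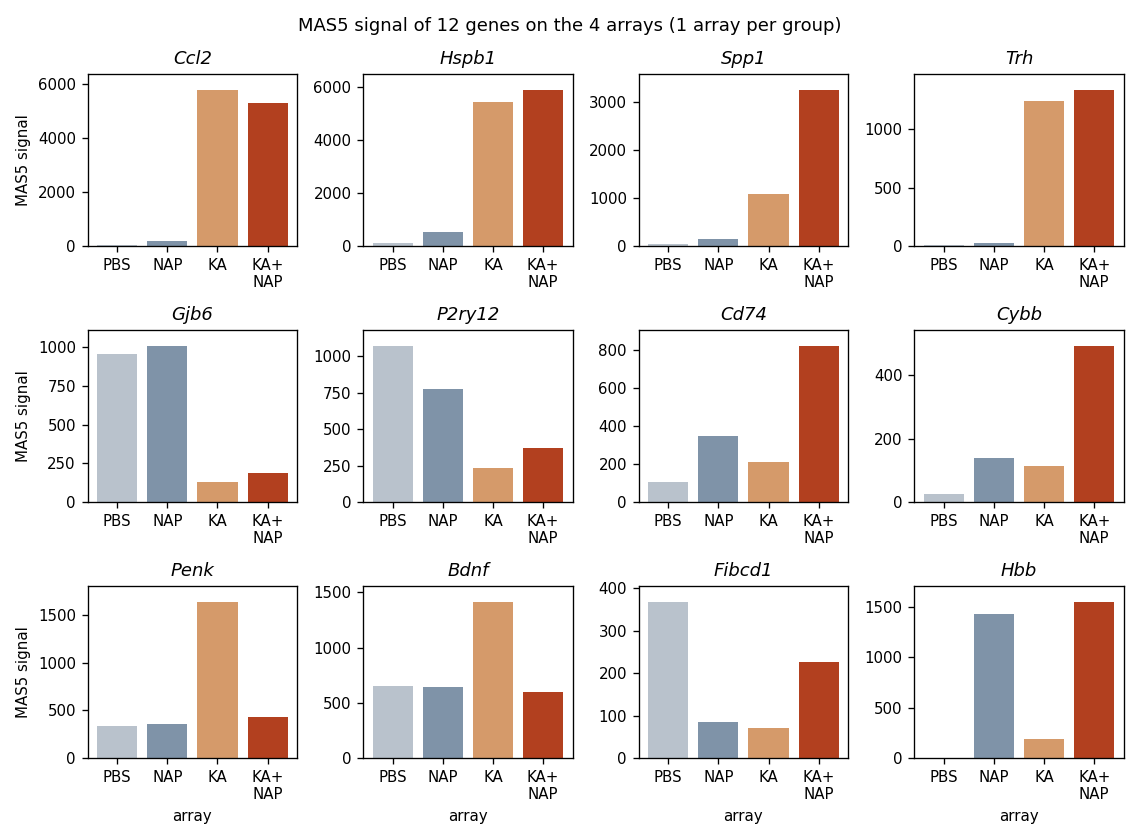
MAS5 intensity (vertical axes, linear and starting at 0) of 12 genes on the 4 arrays, 1 bar per array with no error bars because each group has 1 array. Ccl2, Hspb1, Spp1 and Trh are high on both KA arrays, Penk and Bdnf are high on the KA array only, and Hbb is at 1430 and 1549 on the NAP and KA+NAP arrays.

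Whether the KA response was smaller with NAP was read over genes chosen on the average KA effect. The 437 genes at least 2-fold higher on average had a median of 1.38 in KA minus PBS and 1.41 in KA+NAP minus NAP. Their median interaction was −0.01, with an interval of −0.06 to 0.05 from resampling genes. The interaction was below 0 for 223 of them and above 0 for 213, and it was at least 2-fold negative for 38 and at least 2-fold positive for 17. The 158 genes at least 2-fold lower on average had medians of −1.29 and −1.26 and a median interaction of 0.04 (resampling interval −0.10 to 0.20). Both resampling intervals describe spread across genes on single arrays and leave out variation between animals. A median near 0 within them therefore cannot decide whether NAP changed the KA response. At a threshold of 3-fold, the median interaction was −0.17 for the higher and 0.32 for the lower genes. Over the 437 higher genes, the NAP array lay above the PBS array by a median of 0.33 and the KA+NAP array above the KA array by 0.30. Across all 9489 genes, 334 had an interaction of at least 2-fold, where simulations gave 292 to 380. The simulated noise was drawn from NAP minus PBS, which is part of the interaction and includes any difference between those animals. The simulated range may therefore be too high, and it cannot show whether interactions exceeded array noise.

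The lowest interactions belonged to Prss35 at −3.86, Cbln1 at −3.68, Hbb at −3.59, Rprm at −2.90, Pdyn at −2.73, Abca1 at −2.60, Lox at −2.57 and Crabp2 at −2.48. For Abca1, only 1 of 3 probe sets past the filter had the reported sign in KA minus PBS, and likewise in KA+NAP minus NAP. Rprm differed by 3.94 in KA minus PBS and 1.04 in KA+NAP minus NAP. The highest belonged to Car3 at 4.80, Nts at 3.90, Fibcd1 at 3.50, Pou3f1 at 3.32, the serotonin receptor Htr5b at 2.85, Mpped1 at 2.46, Pts at 2.45 and Nkain3 at 2.43. Each rests on 4 single intensities, and the value and rank of Hbb depend on the pseudocount, because its PBS intensity of 5 lies below it.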

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

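All tests below except those of the dentate granule cell markers and of array noise were chosen only after the result was seen, and before the noise test single genes and list medians of the NAP array had been seen. 7 named genes had KA differences of at least 2-fold in opposite directions without and with NAP, and these differences between the 2 effects were not tested, since each group has 1 array. The interactions were 4.80 for Car3, 3.50 for Fibcd1, 3.32 for Pou3f1, 2.45 for Pts, 2.43 for Nkain3, −2.73 for Pdyn and −3.86 for Prss35. For 2 of the lists fixed in advance, the medians lay on opposite sides of 0 with at least 1 of them outside the random range, also untested. The median of interferon response genes was −0.14 in KA minus PBS and 0.52 in KA+NAP minus NAP, and that of the 3 choroid plexus and ependymal markers was 0.19 and −0.65. Only 3 of the 10 choroid plexus and ependymal markers on the array passed the filter, and their 2 medians are values of different genes. Foxj1 was at 0.19 and 0.58, and Enpp2 at 0.04 and −0.65. Among 3068 probe sets past the filter that the annotation used here does not list, 61 were at least 2-fold higher and 29 at least 2-fold lower in both KA differences.

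Markers of CA1, a neighbour of the dissected CA3, were higher on the KA+NAP array than on the KA array, with a median of 1.07 over 7 CA1 pyramidal markers, 5 of which are also on the fixed list. In NAP minus PBS these markers had a median of −0.55, below the random range of −0.19 to 0.28, with 6 of 7 below 0, while the fixed list, which also holds dentate genes, had 0.33. Since the values of those 5 had been seen, a departure of the KA array alone is not excluded. Unequal shares of CA1 and dentate tissue could give such a pattern, but 9 dentate granule cell markers, then lower on the KA+NAP array, had a median of −0.014 in KA+NAP minus KA, inside the random range of −0.21 to 0.24, while in NAP minus PBS it was 0.35, above the range and opposite to the CA1 markers. Dissection, the KA array and a response of CA1 neurons to KA and NAP all stay open.

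Microglia and macrophage genes were higher on both arrays with NAP (medians 0.61 and 0.99), together with Hbb and meningeal genes. The signal added with NAP in the presence of KA over that added in its absence was 3.78 in the median over the 15 of 19 markers higher on the NAP array than on the PBS array (resampling interval 2.45 to 4.63), 0.956 for Hbb and 0.38 over 7 meningeal markers (0.305 to 0.665). These ratios differ from what blood or meninges of one composition would add as the only source, but that composition is assumed, so neither tissue is excluded. Their resampling intervals leave out variation between animals. The medians of 7 border macrophage markers, 1.29 and 1.66, decide nothing about meningeal macrophages, because 4 of the 7 are antigen presentation genes already seen to be high. These sources and a response to the peptide stay open.

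Genes higher with KA also lay above PBS on the array with NAP alone. Over the 437 genes chosen on the average KA effect, the median of NAP minus PBS was 0.33, and 348 genes lay above 0. Independent array noise of equal size on each array gave −0.0517 to 0.0438 in 100 simulations, which argues against it, and over the 158 lower genes the median was 0.00. A larger injection injury in the NAP animals and a response to the peptide were not tested and both stay open.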

How the results depend on the processing

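No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. One setting, use of the other control array, was chosen after the data were seen. Scaling to equal trimmed means, median scaling, quantile normalization, the lower pseudocount and the mean over probe sets left the 8 counts within 1.5 times and the correlation of the KA effects and both median interactions within their resampling intervals. Counts in the order KA minus PBS, KA+NAP minus NAP, KA+NAP minus KA and NAP minus PBS follow. At 1.5-fold, 1176, 1311, 620 and 376 genes were higher and 907, 890, 272 and 160 lower. At 3-fold, 171, 171, 26 and 30 were higher and 57, 44, 16 and 3 lower. With no filter, 755, 902, 370 and 269 were higher and 447, 433, 194 and 189 lower. With the filter at the 75th percentile, which admits fewer genes, 192, 198, 34 and 37 were higher and 104, 97, 22 and 5 lower. With the pseudocount at the 40th percentile, which shrinks dim genes, 91 genes were higher in KA+NAP minus KA, and 66 were higher and 12 lower in NAP minus PBS. With NAP in place of PBS as the control of KA, 302 genes were higher. The correlation of the KA effects was 0.56 with no filter and 0.73 with the filter at the 75th percentile. The median interaction of the higher genes was −0.17 at 3-fold and −0.0854 with the stricter filter, and that of the lower genes 0.32 at 3-fold. Chosen on KA minus PBS alone, the medians were −0.27 and 0.51, and on KA+NAP minus NAP alone 0.28 and −0.48. Each of these choices shares its noise with the interaction. With the filter at the 75th percentile, 3 list medians that were outside the random range changed sign: CA1 and dentate gyrus markers in KA+NAP minus KA (−0.013), infiltrating myeloid cell markers in KA minus PBS (−0.036) and meningeal and fibroblast markers in KA+NAP minus NAP (0.30). For these and the settings above, the cause was not tested beyond the number of genes each setting admits. 6 other values of list medians lay beyond the resampling interval, among them cytokines and chemokines with that filter (4.27 in KA minus PBS, 4.32 in KA+NAP minus NAP and −0.0525 in KA+NAP minus KA). For the named genes, 50 values moved by more than 0.5 on the log2 scale, all under another pseudocount or the mean over probe sets. No named gene with a difference of at least 2-fold had the opposite sign under any of the scaling, pseudocount, filter and probe set settings.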

Other observations

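No test was run for the values given here. Of the lists with fewer than 3 measured members, the erythrocyte genes had Hbb alone past the filter, at 5 with PBS, 186 with KA, 1549 with KA+NAP and 1430 with NAP. The sex-linked genes had Xist, at 345, 166, 322 and 208 in that order, and Uty, at 505, 558, 416 and 451. Spike-in control probe sets lay above their mean over the arrays by 0.16 on the log2 scale with PBS and 0.05 with KA+NAP, and were at −0.16 with KA and −0.06 with NAP. In all, 182 genes were at least 2-fold higher on each KA array than on either array without KA, and 64 at least 2-fold lower.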
